A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

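Gene expression was measured in the budding yeast Saccharomyces cerevisiae, strain S288C, the laboratory strain whose genome is the reference of the species. Per the labels' protocols, cells growing exponentially in rich YPD medium at 25 °C were exposed to 1.8 mM formaldehyde for 2 h, and a control culture was grown on for 2 h without treatment. Poly(A) RNA was purified, copied into cDNA and labelled with Cy5 (treated) or Cy3 (control), and both were hybridised to one 2-colour array, per the labels. The labels give 3 independent biological samples, 1 array each, and every array was scanned at high and at low laser power so that spots too bright for the first scan could be read in the second. This gave 6 scans of 3 arrays. All arrays carried the treated sample in Cy5, so no dye swap was available and a gene-specific dye effect cannot be separated from the treatment.

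The deposited table holds 1 log2 ratio per probe and scan, which the authors normalised by LOWESS within each scan over spots that carried no flag, per the labels' descriptions. The log base follows from the values: the lowest one, -6.64, is the log2 of a ratio of 0.01, and 2 values lie at it. Spot intensities, background, flags and the authors' merged high and low values were not used here, so the signal over background behind each ratio is unknown, and the number of arrays sets the precision. The image software, and the direction of the ratio, are not given in the sources used here. Values are read as Cy5 over Cy3, that is treated over control. This direction is likely, not settled: it rests on the labels, which put the treated sample in channel 1, and on the usual way of depositing such a ratio. If the ratio ran the other way, every "higher" would read "lower". The mean over probes lay between -0.0087 and 0.0058 in all 6 scans, so each scan was centred near 0, and the medians over probes were -0.0067 and 0.0031 (array 1, high and low power), 0.0032 and 0.071 (array 2), and 0.096 and 0.19 (array 3).

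Of 6912 probes, 5446 had 1 gene symbol in GEO's platform annotation, none had several, and 1466 had none. The named probes covered 5379 genes, and all 5379 gene identifiers were found in the NCBI gene table of the S288C reference, which supplied the systematic names. The build behind the array is not given in the sources used here, so no coordinates are printed. Probes of one gene were averaged. ACT1 was listed on 49 probes with identical values and counted once. Probes without a symbol were left out of the main test.

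For each gene the high and low power log2 ratios of an array were averaged, or the one present was taken, and arrays were the replicates (n = 3). Genes with a value on all 3 arrays were tested (2133 genes). The mean log2 ratio was tested against 0 with limma 3.58.1 in R 4.3.3 (lmFit, eBayes; 2 residual and 4.84 prior degrees of freedom), with Benjamini-Hochberg adjustment and a threshold of adjusted p under 0.05. Errors are SDs over the 3 arrays. Lists of yeast pathways, complexes, stress regulons, growth phase, mating type and sporulation genes were fixed before the data were examined, as were the design, most of the other settings tried and the rule for named genes. Of 35 lists, 28 had at least 4 tested members and entered limma's camera test (preset correlation of 0.01, Benjamini-Hochberg over the 28 lists). An older symbol shared by 2 genes was taken for neither. Camera was repeated with an estimated correlation, and limma's fry, which asks whether a list's genes move on balance one way, was run beside it. On simulated ratios for the 2133 genes, the gene test recovered 72.0% of genes changed by 1 on the log2 scale. It recovered 99.0% of those changed by 2, and 1.16% of its calls were false. In that run 100 genes were changed by each amount, and variances came from the prior fitted to the real arrays. The test's own assumptions thus held, and the shares need not apply to the real arrays, where most tested genes were called. Of 28 simulated lists of 20 genes, camera with the preset correlation and fry called the 1 shifted list and no other, whereas camera with an estimated correlation gave it an adjusted p of 0.18. The simulated genes were drawn independently of each other. The run therefore cannot show how the preset correlation fares on lists whose genes move together between arrays.

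The named genes are the 12 largest increases and the 12 largest decreases among called genes with one sign on all arrays, the genes SFA1, YJL068C, FDH1, GSH1, GSH2 and GLR1, and for each list its 4 members of largest change (lists past a test, or with 3 or more called members) or 2 (other lists). The alternatives tried were: each scan power alone, 6 scans with the array as a random block, centring or scaling of the scans, other filters on missing values, robust eBayes, single probes, a minimum fold, a stricter threshold, and leaving out each array. A fit without 1 array rests on 2 arrays and 1 residual degree of freedom, so its p-values lean on the variance pooled over genes. They can be far smaller than on 3 arrays (ATG41 by limma: adjusted p = 4.28e-41 without array 1, 1.13e-05 in the main test). Such p-values, and calls gained or lost by them, are not like measures beside the main test. The 2 scan powers were compared within arrays by limma.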

Results

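Treated and untreated cultures were compared within each of 3 arrays, and the arrays differed in how many genes they measured. Array 1 gave a log2 ratio for 2498 genes, array 2 for 3329 and array 3 for 4292, out of 5379. The low power scans covered 751 to 1471 genes and the high power scans 2487 to 4287. All 3 arrays had a value for 2133 genes, 2 arrays for 1174 genes, 1 array for 1372 and none for 700. Across the 2133 genes, Pearson's r between arrays was 0.902 (arrays 1 and 2), 0.886 (1 and 3) and 0.948 (2 and 3); these are correlations across genes, which are not independent replicates. The median SD of a gene over the arrays was 0.29 on the log2 scale. All ratios are given as treated over control, the likely direction: the labels put the treated sample in channel 1 (Cy5) on every array, but the direction of the ratio is not stated, and if it were turned every higher and lower would swap.

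The question put by the design is which transcripts change in abundance when yeast is held in 1.8 mM formaldehyde for 2 h. By camera with a preset correlation, the lists of sulfur assimilation and methionine synthesis, glutathione metabolism and the proteasome were higher, and those of cytosolic ribosomal proteins, glycolysis, sterol synthesis and histones were lower. None of these calls held with an estimated correlation (adjusted p = 0.36 or more). With that setting camera also missed the shifted list of the simulation (adjusted p = 0.18), so a miss there does not decide against a list. It does not show that the preset calls hold either. Of the 2133 genes, 794 were higher and 539 lower at adjusted p under 0.05 (limma), and 800 did not pass. The 2546 genes left out with a value on 1 or 2 arrays had a median of -0.15, so this split may understate the falls. When 2 arrays sufficed, 1003 were higher and 816 lower. At least 2-fold changes were called for 469 genes upward and 334 downward, and at least 8-fold changes for 44 upward and 73 downward. Of the 1333 called genes, 1326 had one sign on all 3 arrays. The median log2 ratio of all tested genes was 0.18 as deposited, and fell to 0.075 when scans were centred on genes other than ribosomal protein genes. Changes of that size are therefore not distinguished from the choice of zero. Both zeros come from the measured genes themselves, and 62.5% of the tested genes were called. A shift shared by most transcripts would not be seen, so every higher or lower is relative to that zero.

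The largest increase was that of FLR1 (YBR008C), a plasma membrane multidrug transporter, at 6.53 ± 0.45 on the log2 scale (SD, n = 3), or 92.3-fold. MET17 (YLR303W), which makes homocysteine from sulfide, followed at 6.20 ± 0.08, or 73.4-fold. The putative aryl-alcohol dehydrogenase AAD14 rose by 5.59 ± 0.51 and the hexose transporter HXT5 by 5.51 ± 0.25. The remaining genes among the 12 largest increases were MET3 (4.86 ± 0.09), MET10 (4.68 ± 0.47), the amino acid permeases MUP3 (4.68 ± 0.51) and MUP1 (4.44 ± 0.33), the glutathione transferase ECM4 (4.43 ± 0.31), and YLR460C (4.62 ± 0.80), YML131W (4.55 ± 0.17) and YCR102C (4.50 ± 0.34), known by their systematic names. Their adjusted p lay between 5.94e-06 and 2.27e-05. AAD14, HXT5, YLR460C and YCR102C belong to families of similar genes, between which cDNA may cross-hybridise on an array.

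The largest decreases were dominated by ribosomal protein genes. RPL1B (YGL135W) fell by 5.03 ± 0.59 on the log2 scale and its copy RPL1A (YPL220W) fell by 4.87 ± 0.20. RPS8B, RPL9B, RPS4A, RPL11B, RPL11A, RPS0A and RPL32 had mean log2 ratios between -4.62 and -4.23. ASC1, counted with them as a component of the small subunit, fell by 4.51 ± 0.28. Outside that class, translation elongation factor 3 (YEF3, YLR249W) fell by 4.62 ± 0.62 and the glucose transporter HXT2 fell by 4.55 ± 0.14. Their adjusted p lay between 8.04e-06 and 1.28e-05.

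**Figure D1:**
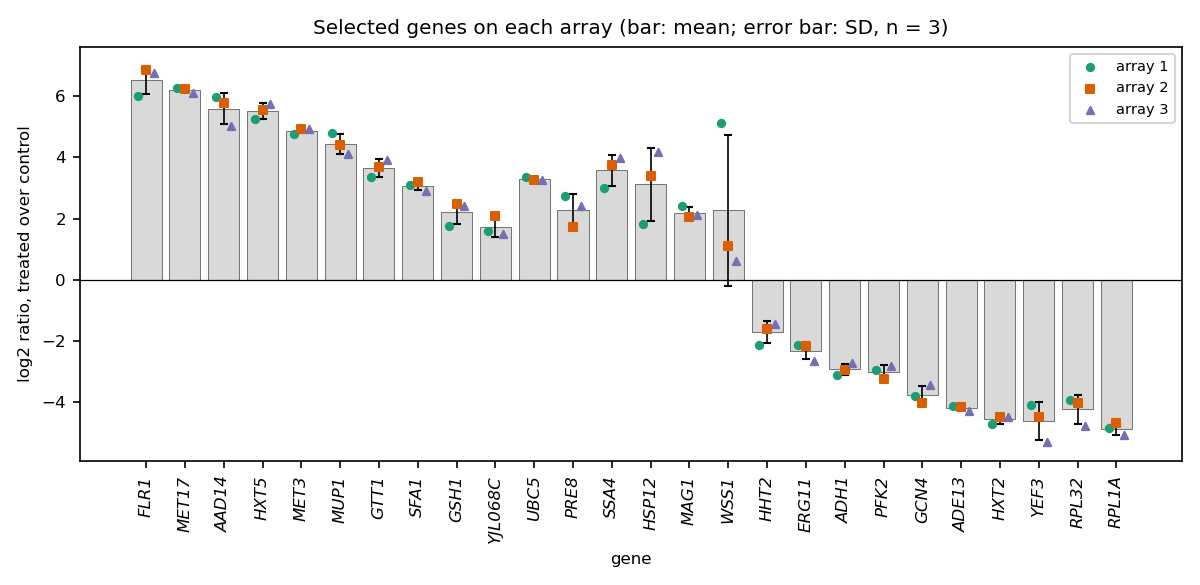
Log2 ratio (treated over control) of 26 named genes; bars are means, error bars SDs over 3 arrays, and symbols single arrays. FLR1 and MET17 stand above 6 and RPL1A below -4 on the mean, and WSS1 is the gene whose mean rests on array 1.

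Genes of formaldehyde oxidation and glutathione metabolism rose together. Of 14 measured members, 13 rose and none fell (13 adjusted over the list alone), with a median log2 ratio of 1.62. SFA1 (YDL168W), the glutathione-dependent formaldehyde dehydrogenase, rose by 3.06 ± 0.14, or 8.32-fold. YJL068C, the S-formylglutathione hydrolase of the next step, rose by 1.72 ± 0.31, or 3.30-fold. GSH1, which starts glutathione synthesis, rose by 2.22 ± 0.40, GSH2, which completes it, by 0.81 ± 0.25, and the glutathione reductase GLR1 by 1.13 ± 0.21. The glutathione transferase GTT1 rose by 3.65 ± 0.29, DUG3, of glutathione degradation, by 2.44 ± 0.24 and the glutaredoxin GRX2 by 2.43 ± 0.19. FDH1, a formate dehydrogenase, had a value on 1 array and was not tested. The list passed camera with adjusted p = 0.000398, and had adjusted p = 0.36 with an estimated correlation. GSH2 lost its call without array 2 (0.71 on the log2 scale, adjusted p = 0.052).

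Sulfur assimilation and methionine synthesis showed the largest upward median of the tested lists, 2.25. Of 21 measured genes 18 rose, led by MET17, MET3 (ATP sulfurylase), MET10 (a sulfite reductase subunit) and MUP3, and 3 fell (18 and 3 adjusted over the list alone). The 3 that fell, named after their values were seen, were SAM4 at -2.26 ± 0.24, HOM2 at -2.02 ± 0.02 and SAH1 at -1.87 ± 0.30; they act in the reuse of S-adenosylmethionine, in the synthesis of homoserine and in the hydrolysis of S-adenosylhomocysteine. The oxidative stress list of Yap1 targets had a median of 2.09, with 16 of 18 measured genes higher and 2 lower (16 and 2 adjusted over the list alone). FLR1, AAD14, ECM4 and the reductase GRE2 (3.97 ± 0.50) led it. Camera gave adjusted p = 0.000582 for the sulfur list and 0.000178 for the oxidative stress list; each had adjusted p = 0.36 with an estimated correlation. With low power scans alone, the sulfur list missed the threshold at a median of 2.20 (adjusted p = 0.18).

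Subunits of the proteasome, the main protease for ubiquitin-tagged proteins, rose nearly as a block. Of 31 measured subunits, 27 rose and none fell (27 adjusted over the list alone), with a median log2 ratio of 1.38. The core particle subunits PRE8 (2.29 ± 0.50), PRE2 (2.18 ± 0.22), PRE4 (2.17 ± 0.31) and PRE1 (1.97 ± 0.31) had the largest increases. In the list of ubiquitin and protein quality control, 11 of 13 rose and none fell (11 adjusted over the list alone), among them the ubiquitin-conjugating enzyme UBC5 (3.30 ± 0.06), DDI1 (3.00 ± 0.58), the proteasome assembly factor UMP1 (2.67 ± 0.24) and UFD1 (1.73 ± 0.16). Camera gave adjusted p = 2.38e-05 for the proteasome, with adjusted p = 0.52 with an estimated correlation, and adjusted p = 0.000582 for quality control, with 0.36 with an estimated correlation.

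Heat shock chaperones and general stress genes changed in part. Of 20 measured chaperone genes 12 rose, 1 fell and 7 did not pass (12 and 1 adjusted over the list alone). The Hsp70 gene SSA4 rose by 3.57 ± 0.52, HSP42 by 2.05 ± 0.72, HSP10 by 1.88 ± 0.22 and AHA1 by 1.72 ± 0.59. Of 28 general stress genes 15 rose, 3 fell and 10 did not pass (15 and 3 adjusted over the list alone); TFS1 rose by 3.63 ± 0.26, ALD3 by 3.40 ± 0.32, DDR2 by 3.34 ± 0.91 and HSP12 by 3.13 ± 1.19. Medians differed between arrays: 0.38, 0.93 and 1.08 for the chaperones and 0.23, 0.79 and 1.31 for the general stress genes on arrays 1, 2 and 3. The chaperone list passed camera at adjusted p = 0.0456 (adjusted p = 0.75 with an estimated correlation, 0.085 by fry, 0.091 without array 3, 0.47 with low power scans alone). The general stress list did not pass camera, at adjusted p = 0.0503. It passed without array 1 (median 1.07, adjusted p = 2.14e-05) and without array 2 (median 0.65, adjusted p = 0.0103). Those fits rest on 2 arrays each, so their p-values are not comparable with that of the main test. The list's median was 0.47 without array 3.

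DNA repair genes mostly lacked a value on at least 1 array, and 27.5% had one on all 3. Of 11 measured genes 8 rose and none fell (8 adjusted over the list alone), with a median of 1.47. The median was 0.47 over the 30 members with a value on array 3 and 0.086 over the 22 with a value on 1 or 2 arrays. RAD59 rose by 3.32 ± 0.77, the DNA helicase SSL2 by 2.08 ± 0.13 and RAD6 by 1.71 ± 0.34. WSS1, a protease for proteins crosslinked to DNA, was called at 2.27 ± 2.47, but its values were 5.10, 1.10 and 0.61 on arrays 1, 2 and 3. Its adjusted p was 0.16 with robust eBayes. Its log2 ratio was 0.86 without array 1 (limma adjusted p = 0.00529, on 2 arrays and leaning on the pooled variance). The list passed camera at adjusted p = 0.0221 (adjusted p = 0.55 with an estimated correlation) and lost the call without array 1, with a median of 0.69 (adjusted p = 0.10), while the median was 0.79 without array 2 (adjusted p = 0.0189). In the separate DNA damage response list of 5 measured genes, the DNA glycosylase MAG1 rose by 2.19 ± 0.19 and the photolyase PHR1 by 0.70 ± 0.43, while DUT1 fell by 1.62 ± 0.08 and the ribonucleotide reductase subunit RNR4 fell by 0.99 ± 0.39 (2 higher and 2 lower adjusted over the list alone), and the list did not pass (camera adjusted p = 0.77). PHR1 lost its call without array 2 (0.54, adjusted p = 0.15) and without array 3 (0.62, adjusted p = 0.12).

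All 68 measured cytosolic ribosomal protein genes fell (68 adjusted over the list alone). Their median log2 ratio was -3.52, with array medians of -3.44, -3.29 and -3.80 (camera adjusted p = 2.45e-33; adjusted p = 0.36 with an estimated correlation). Many of these genes exist as near-identical pairs, such as RPL1A and RPL1B, so values of the 2 copies are not independent. The 13 members without a paralogous copy had a median of -3.82 and the 55 others -3.47. Mitochondrial ribosomal proteins did not pass as a list (camera adjusted p = 0.20): 2 rose, 8 fell and 19 of 29 did not pass (2 and 5 adjusted over the list alone), with a median of 0.018, and camera's direction was downward. The median was -0.052 with centred scans, and -0.10, -0.064 and -0.29 without arrays 1, 2 and 3, so its sign is not settled. RSM28 and MRPL37, named after their values were seen, were high on array 1 alone (4.05 and 3.41) and did not pass. MRPL20 fell by 1.79 ± 0.33, MNP1 fell by 1.52 ± 0.24 and MRPL49 fell by 1.01 ± 0.49, and MRP8 rose by 1.33 ± 0.39.

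Ribosome biogenesis genes and RNA polymerase I and III subunits could hardly be tested. Of 83 biogenesis genes on the array, 2 had a value on all 3 arrays: DBP2, which fell by 1.96 ± 0.38, and ENP2, at -0.41 ± 0.39 (1 lower adjusted over the list alone). On array 3, which measured most genes, 49 of them had a value; all 49 were below 0, with a median of -2.18. Of 23 RNA polymerase I and III subunits none had a value on all arrays, and 11 of 13 with a value on array 3 were below 0 (median -1.25). These are single-array values without a test.

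**Figure D2:**
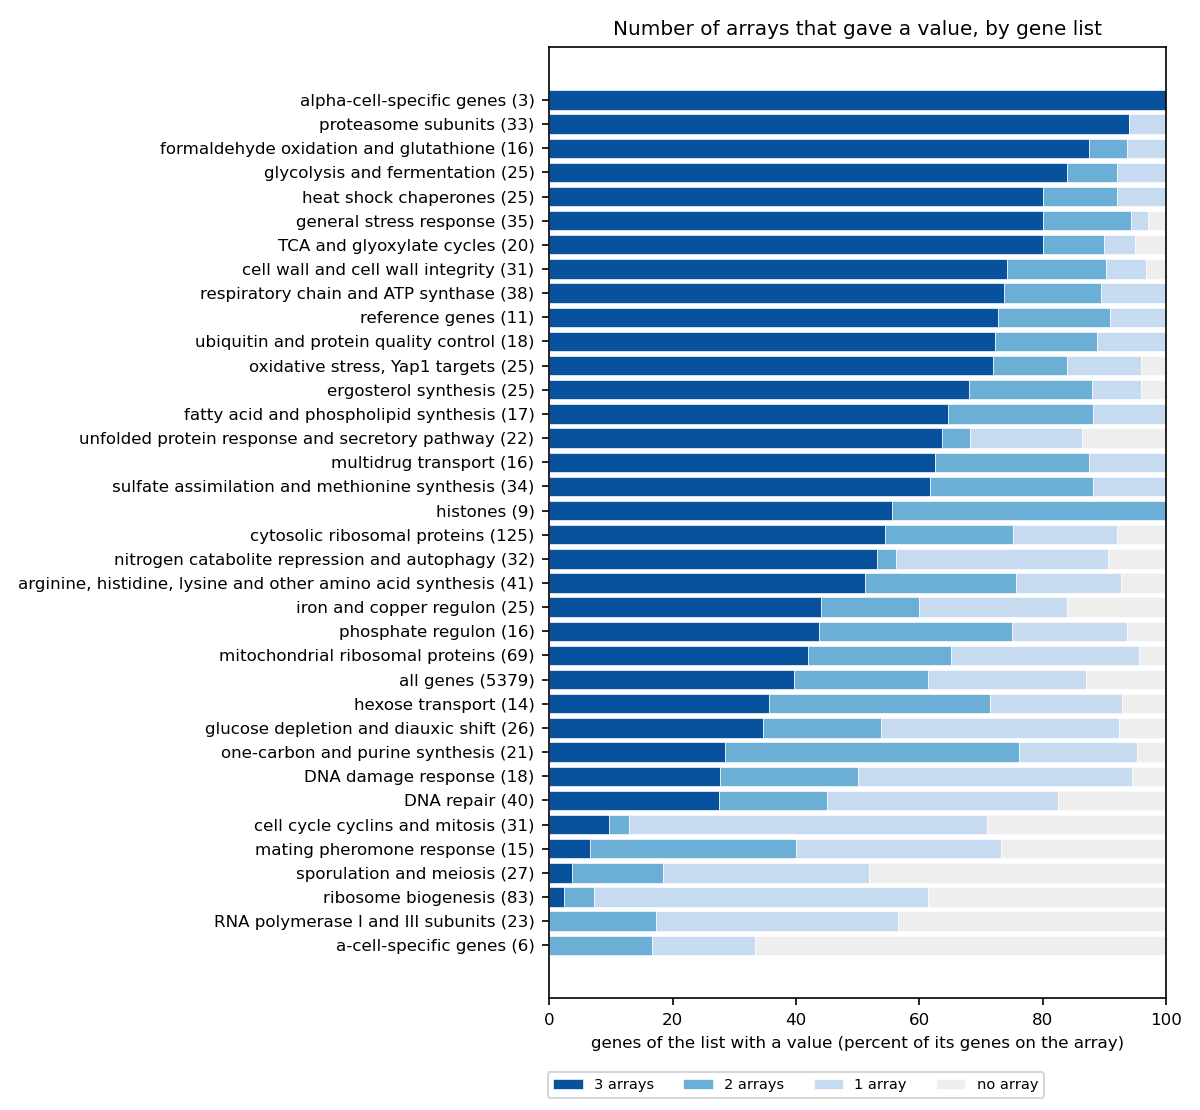
Share of each list's genes on the array (percent, horizontal axis; number of genes in parentheses) that had a log2 ratio on 3, 2, 1 or no array. Proteasome subunits (93.9% on 3 arrays) and ribosome biogenesis genes (2.41%) lie near opposite ends.

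Genes of glycolysis and fermentation fell for the most part. Of 21 glycolytic and fermentative genes 15 fell and 4 rose (15 and 4 adjusted over the list alone), with a median of -1.30; the acetyl-CoA synthetase ACS2 fell by 3.57 ± 0.24, the phosphofructokinase subunit PFK2 fell by 3.01 ± 0.22, the pyruvate decarboxylase PDC1 fell by 3.00 ± 0.05 and the alcohol dehydrogenase ADH1 fell by 2.92 ± 0.19. The 4 that rose, named after their values were seen, were ALD4 (1.43 ± 0.49), TDH2 (0.80 ± 0.01), TDH1 (0.65 ± 0.23) and TDH3 (0.60 ± 0.22); the last 3 encode the same enzyme, glyceraldehyde-3-phosphate dehydrogenase, and are similar in sequence. TDH1 lost its call without array 2 (0.71, adjusted p = 0.051) or array 3 (0.51, adjusted p = 0.084), and TDH3 without array 1 (0.50, adjusted p = 0.12) or array 3 (0.59, adjusted p = 0.083). Camera gave the list adjusted p = 0.00016, and adjusted p = 0.37 with an estimated correlation. Among respiratory chain and ATP synthase genes 11 of 28 fell and 4 rose (11 and 4 adjusted over the list alone); COX4 fell by 2.52 ± 0.37, ATP4 fell by 1.48 ± 0.10, COX6 fell by 1.41 ± 0.17 and ATP7 fell by 1.25 ± 0.09. That list passed camera at 0.0289, but not with an estimated correlation (adjusted p = 0.52), by fry (0.057), without array 1 (0.19), without array 2 (0.079) or with low power scans alone (0.33). The tricarboxylic acid and glyoxylate cycle list, with 8 of 16 lower and 3 higher (8 and 3 adjusted over the list alone), had a median of -0.48 and camera adjusted p = 0.058. Without array 3 the adjusted p was 0.044, and without array 1 the median was -0.18 (adjusted p = 0.42). ACO1 fell by 2.77 ± 0.20, IDH2 fell by 1.96 ± 0.01, IDH1 fell by 0.96 ± 0.19 and MDH2 fell by 0.72 ± 0.32. MDH2 lost its call without array 1 (-0.57, adjusted p = 0.069) or array 2 (-0.68, adjusted p = 0.064).

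Genes that mark glucose depletion went both ways. Of 26 on the array, 9 were measured on all 3 arrays (median -0.09), while 15 with a value on 1 or 2 arrays had a median of 1.30. The list's median was 0.46, 0.72 and -0.35 without arrays 1, 2 and 3, and 0.10 with high power scans alone, settings that also change which genes are measured, so its sign is not settled. Of the 9, 3 rose and 3 fell (3 and 3 adjusted over the list alone): HXT5 rose, and HSP30 rose by 2.87 ± 0.45, while ADH2 fell by 2.90 ± 0.47 and HXT6 fell by 2.12 ± 0.50 (camera adjusted p = 0.77). HXT6 and ADH2 each have a close relative with a similar mean log2 ratio, HXT7 (-2.11) and ADH1 (-2.92). Their falls may therefore not be separate from those of the relatives, as cDNA may cross-hybridise. In the separate hexose transport list HXT2, HXT4 (-3.09 ± 0.35) and HXT3 (-1.05 ± 0.36) fell among 5 measured (3 adjusted over the list alone), and the list had adjusted p = 0.082 (0.022 without array 2). Its median was -1.05 over these 5, -0.25 without array 1, and 0.11 over 8 members with a value on 1 or 2 arrays.

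Sterol synthesis, purine synthesis and histones fell. Of 17 ergosterol genes 14 fell and 1 rose (14 and 1 adjusted over the list alone; median -1.17), led by ERG1 (-2.69 ± 0.23), ERG11 (-2.31 ± 0.29), ERG6 (-1.88 ± 0.29) and ERG2 (-1.75 ± 0.15). Of 6 one-carbon and purine genes 5 fell (5 adjusted over the list alone; median -1.67): ADE13 fell by 4.17 ± 0.09, ADE12 fell by 2.75 ± 0.31, GCV3 fell by 1.68 ± 0.11, ADE8 fell by 1.65 ± 0.33, and ADE16, outside the naming rule, fell by 1.37 ± 0.17. All 5 measured histone genes fell (5 adjusted over the list alone; median -1.57), among them HHT2 (-1.71 ± 0.36), HHF1 (-1.58 ± 0.57), HHT1 (-1.57 ± 0.18) and HTB1 (-1.56 ± 0.12); histone genes come in near-identical pairs. Camera gave adjusted p = 7.82e-05 for sterols, 0.00348 for purines and 0.00347 for histones, and each list had adjusted p = 0.36 with an estimated correlation.

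Amino acid synthesis outside the sulfur pathway was divided: 11 of 21 genes fell and 4 rose (11 and 4 adjusted over the list alone; median -0.50, camera adjusted p = 0.0446, adjusted p = 0.36 with an estimated correlation). GCN4, the transcriptional activator of the pathway genes, fell by 3.75 ± 0.29, HIS1 fell by 3.08 ± 0.09 and HIS4 fell by 2.25 ± 0.17, and LYS1 rose by 3.01 ± 0.16. Cell wall genes were likewise divided, with 13 of 23 lower and 5 higher (13 and 5 adjusted over the list alone; median -0.71, camera adjusted p = 0.0303, adjusted p = 0.36 with an estimated correlation). GAS1 fell by 3.73 ± 0.38, SCW11 fell by 2.02 ± 0.21 and CHS3 fell by 1.68 ± 0.08, while PIR3 rose by 2.30 ± 0.15. With low power scans alone the amino acid list had adjusted p = 0.47 and the cell wall list 0.16, and the cell wall list had 0.073 without array 1.

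**Figure D3:**
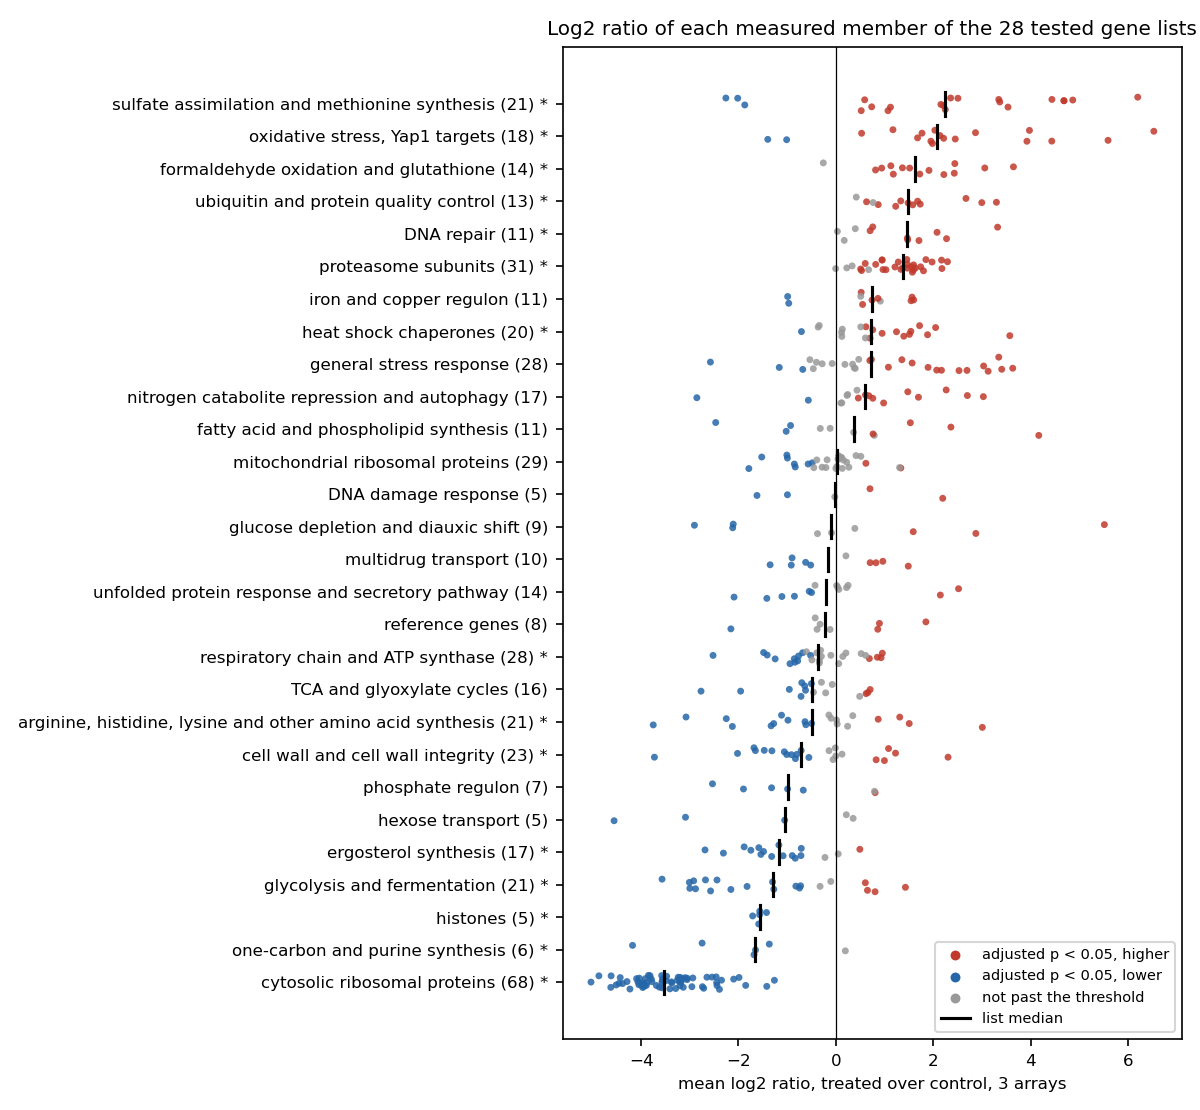
Mean log2 ratio (treated over control, 3 arrays) of every measured member of the 28 tested lists; black bars are list medians, parentheses give the number measured and asterisks mark camera adjusted p under 0.05. The 68 ribosomal protein genes lie below -1 and the sulfur list has the highest median, 2.25.

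Some called members of these lists moved against most of the others; they fall outside the naming rule and were chosen after their values were seen; of the other settings, only leaving out an array was run for them. The Hsp90 gene HSC82 fell by 0.71 ± 0.17 among the chaperones. In the general stress list GSY1 (-2.58 ± 0.66), GPH1 (-1.16 ± 0.54) and GLC3 (-0.68 ± 0.57), of glycogen metabolism, fell, and in the oxidative stress list GND1 (-1.40 ± 0.10) and TAL1 (-1.01 ± 0.12), of the pentose phosphate pathway. Members that rose in lists with more falls were SER3 (1.51 ± 1.04), TRP5 (1.31 ± 0.20) and HIS5 (0.87 ± 0.35) of amino acid synthesis, CYC7 (0.95 ± 0.83), SDH4 (0.93 ± 0.47), COX9 (0.85 ± 0.16) and ATP18 (0.69 ± 0.33) of the respiratory chain, and PYC1 (0.70 ± 0.32), LSC1 (0.66 ± 0.11) and IDP1 (0.62 ± 0.14) of the tricarboxylic acid list. ERG9 rose by 0.49 ± 0.08 in sterol synthesis, and TIP1 (1.22 ± 0.22), CCW14 (1.08 ± 0.13), SED1 (1.00 ± 0.10) and BGL2 (0.83 ± 0.11) rose among the cell wall genes. Without array 1, SER3 was at 0.92 (adjusted p = 0.00253), and GLC3 at -0.39 (adjusted p = 0.24) and ATP18 at 0.54 (adjusted p = 0.090) lost their calls. Without array 2, calls were lost for GLC3 (-0.70, adjusted p = 0.060), HSC82 (-0.65, adjusted p = 0.076), LSC1 (0.59, adjusted p = 0.11) and IDP1 (0.63, adjusted p = 0.089). Without array 3 they were lost for CYC7 (0.58, adjusted p = 0.18), SDH4 (0.72, adjusted p = 0.059), PYC1 (0.53, adjusted p = 0.083), IDP1 (0.55, adjusted p = 0.073) and ATP18 (0.66, adjusted p = 0.080). ERG9 lost its call whichever array was left out (0.45 to 0.52, adjusted p = 0.10 to 0.17). The fifth histone gene that fell was HHO1, of the linker histone, at -1.42 ± 0.20, and the third glucose depletion gene that rose was FOX2, at 1.59 ± 0.44.

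Other lists did not pass camera. In the unfolded protein response list (adjusted p = 0.27; 2 of 14 higher, 6 lower, 2 and 5 adjusted over the list alone) ERO1 rose by 2.52 ± 0.41 and ERV29 by 2.14 ± 0.22, and PMT2 fell by 2.09 ± 0.09 and SEC63 fell by 1.42 ± 0.09. In the multidrug transport list (adjusted p = 0.68, with 4 of 10 higher and 5 lower, also adjusted over the list alone) TPO1 rose by 1.49 ± 0.38 and SNQ2 by 0.96 ± 0.34, and QDR2 fell by 1.35 ± 0.51 and PDR5 fell by 0.92 ± 0.14. The multidrug transporter FLR1, at 6.53 ± 0.45, was counted in the oxidative stress list and not among these 10, so the list does not cover all such transporters. In the phosphate regulon (adjusted p = 0.0509, 0.000561 without array 1 and 0.0451 without array 2; 5 of 7 lower, 1 higher, 5 and 2 adjusted over the list alone) PHO84 fell by 2.53 ± 0.27, SPL2 fell by 1.90 ± 0.09, VTC4 fell by 1.32 ± 0.11 and VTC1 fell by 0.99 ± 0.45. In the iron and copper regulon (adjusted p = 0.18; 7 of 11 higher, 2 lower, 8 and 2 adjusted over the list alone) ARN1 rose by 1.60 ± 0.13, FIT2 by 1.56 ± 0.49 and FRE6 by 1.54 ± 0.15, and the iron oxidase FET3 fell by 0.99 ± 0.37. In the nitrogen and autophagy list (adjusted p = 0.082; 10 of 17 higher, 2 lower, also adjusted over the list alone) APE1 rose by 3.03 ± 0.29, ATG8 by 2.70 ± 0.58 and ATG1 by 2.26 ± 0.44, and GDH1 fell by 2.85 ± 0.07. In the lipid synthesis list (adjusted p = 0.81; 4 of 11 higher, 3 lower, also adjusted over the list alone) OPI3 rose by 4.17 ± 0.22, CPT1 by 2.36 ± 0.34 and CHO2 by 1.53 ± 0.28, and the desaturase OLE1 fell by 2.47 ± 0.24. By fry, the hexose transport and phosphate lists (adjusted p = 0.0101 each) and the iron list (0.0135) passed.

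Mating type, sporulation and reference genes were examined as markers of the culture. None of 6 a-cell-specific genes on the array had a value on all arrays, and of 3 alpha-cell-specific genes STE3 fell by 3.09 ± 0.61 and MF(ALPHA)2 fell by 2.45 ± 0.48 (2 adjusted over the list alone). One gene each of the sporulation list (SPR1, 1.86 ± 0.66) and of the pheromone response list (PRM4, 1.25 ± 0.27) had values on all arrays, and both rose (also adjusted over each list alone). Of 3 measured cell cycle genes, CLN3 fell by 1.74 ± 0.65 and RFA1 rose by 1.32 ± 0.60 (1 and 1 adjusted over the list alone). Of 8 genes often used as references, ACT1 was at -0.12 ± 0.24 (adjusted p = 0.58), whereas FBA1 fell by 2.16 ± 0.55 and CMD1 rose by 1.85 ± 0.29, SPT15 by 0.89 ± 0.14 and PDA1 by 0.86 ± 0.05 (3 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.81).

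High and low power scans of one array gave similar ratios. Pearson's r across genes with both scans was 0.968, 0.960 and 0.974 on arrays 1, 2 and 3 (740, 1145 and 1466 genes). The high power ratio was lower by 0.05, 0.14 and 0.18 on average, with an SD over genes of 0.32, 0.39 and 0.29. Among 546 genes with both scans on all arrays, limma called 0 differences between the powers at adjusted p under 0.05, and 28 had an unadjusted p under 0.05.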

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

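The count below was taken from probes outside the comparisons of the report, a choice made after the data were seen. Of 1466 probes without a gene symbol, 325 had a value in some scan and 60 on all 3 arrays. When they were tested together with the named genes, 38 of the 60 differed between the treated and control channels at adjusted p under 0.05 (limma), 22 higher and 16 lower. The largest decrease was that of probe 3050603, at -4.20 ± 0.60 on the log2 scale (SD, n = 3), and the largest increase that of probe 7120404, at 2.00 ± 0.52. Outlying samples were not sought, because a group of 3 is too small, and the study has no second group in which the treatment was repeated.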

How the results depend on the processing

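Centring on non-ribosomal-protein genes and adding unnamed probes were chosen after seeing the data; the other settings were planned. No called gene changed sign in any setting that tested it. Low power scans alone tested 370 of the 1333 calls, and a value in both scans of all arrays 360. Robust eBayes, the minimum fold, the threshold of 0.01 and the 2-fold mean keep the same mean ratios, so no sign could change there. Of 794 higher and 539 lower genes (1333), low power scans alone called 225 and 178 (403 of 560 tested), a value in both scans of all arrays 226 and 182 (408 of 546), treat with a minimum fold of 1.5 gave 414 and 306 (720), and a 2-fold mean 469 and 334 (803); the first pair tests fewer genes, and the other pair asks for larger changes. Requiring 2 arrays raised the lower calls to 816 (1003 higher), with 3307 genes tested. Leaving out an array gave 608 to 960 higher, 464 to 688 lower and 1072 to 1648 in all, and kept 1053 to 1163 of the 1333 calls. Those fits rest on 2 arrays and a changed set of genes, so their counts are not like measures beside the main ones. Other settings stayed within 1.5 times, and the share of higher calls lay between 53.9% (centred on non-ribosomal-protein genes) and 59.6%. Of 133 named genes, 119 kept their side of the threshold in every setting that measured them. The others missed the minimum fold, the 2-fold mean or the threshold of 0.01, and of these WSS1 also lost its call with robust eBayes and MDH2, GSH2 and PHR1 lost theirs when an array was left out. Of the 15 lists called by camera (7 higher, 8 lower), 0 (0 and 0) passed with an estimated correlation, where the smallest adjusted p was 0.36. That setting missed the simulated shift too. The simulated genes were independent, so this does not show that the preset calls hold for genes that move together. Low power scans alone called 5 lists (2 higher, 3 lower), with fewer members measured, and fry called 16. Leaving out an array gave 14 to 18 lists (6 to 8 higher, 7 to 10 lower); the heat shock, DNA repair, respiratory and cell wall lists each lost their call in at least 1 such setting. The general stress list passed with centred scans (0.0466), with scans centred on non-ribosomal-protein genes (0.0417) and with high power scans alone (0.0371). The comparison of scan powers gave 1 gene in place of 0 when 2 arrays sufficed; the cause was not tested. The main test is itself paired, since each ratio sets treated against control on 1 array, and no other pairing was tried. Spots without a ratio limit the coverage: 39.7% of genes were tested, and signal over background is not known.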

Other observations

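Of the tests in this part, those of chance, and of missing values on genes that are low in treated cells, were set before their results were seen; the others, and the 4 gene families that follow, were chosen afterwards. Of 20 cytosolic aminoacyl-tRNA synthetases on the array 9 were measured, of which 8 fell and none rose (median log2 ratio -2.01), with DED81 at -2.67 ± 0.51 and MES1 at -2.52 ± 0.16 (SD, n = 3). Of 36 initiation and elongation factors 20 were measured, of which 16 fell and none rose (median -1.41), among them TIF3 at -3.46 ± 0.16 and the elongation factor EFT2 at -2.77 ± 0.06. Of 23 genes of GDP-mannose synthesis and protein mannosylation 17 were measured, of which 14 fell and none rose (median -1.24), with PMT4 at -3.06 ± 0.09 and PSA1 at -2.46 ± 0.50. Of 36 ATG genes, which serve autophagy, 14 were measured, of which 12 rose and 1 fell (median 1.02), led by ATG41 at 3.70 ± 0.35 and ATG40 at 2.88 ± 0.76. The 4 families were drawn after the gene table had been read, so their counts describe genes chosen for the pattern and no test of the families is given.

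Exchanging treated and control on 1 array at a time allows 4 sign patterns of the 3 arrays. The real pattern called 1333 genes and the highest of the others called 0. With 4 patterns a share under 0.05 is out of reach.

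The fall of all 68 measured ribosomal protein genes was weighed against 2 technical explanations. Cross-hybridisation between paralogous copies would spare genes without a copy, but the 13 such genes had a median of -3.82, with an SD of the array medians of 0.24, and the least changed was at -1.26. For a bias on bright spots, members were split by their low power values. The 19 with no low power value on any array had a median of -3.47, with an SD of the array medians of 0.38, against -3.56 for the 19 with one on all arrays. A low power value may be missing because the treated channel was weak, and intensities are not known, so this split cannot decide. The 541 genes outside the list with a low power value on all arrays had a median of 0.15 (SD of the array medians 0.11). They did not share the fall of the 19 ribosomal protein genes with such values. This argues, for those 19, against a bias common to all spots read at low power. A bias limited to the brightest of these spots stays open. A gene-specific dye effect also stays open, as no array had the dyes exchanged. A response of treated cells is the hypothesis given by the design and stays open beside these.

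Ribosome biogenesis and RNA polymerase I and III genes had few complete measurements, 2 of 106 on all 3 arrays and 42 with no value. Values may be missing where treated cells hold little of the transcript, which these data leave open. The 62 members with a value on 1 or 2 arrays had a median log2 ratio of -1.87, against -0.12 for 2484 other genes with as many arrays, a difference of -1.75 (two-sided permutation test, 100000 resamples, p = 1e-05, the smallest they can give), but any list that fell would pass this test. Cytosolic ribosomal protein genes fell further, and 54.4% of them had a value on all arrays, against 39.7% of all genes. Shares differed widely between other lists, such as 84.0% for glycolysis and fermentation and 27.5% for DNA repair. The share that ribosomal protein genes would have without a fall is not known, so this comparison does not decide. Low abundance in both cultures may contribute and cannot be told apart, since the table holds no intensities; the share measured on all arrays was 1.89%, against 19.7% for the DNA repair and cell cycle lists (Fisher's exact test, two-sided, p = 6.53e-05).

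General stress and heat shock genes were lower on array 1 than on array 3. All 48 measured members had a higher log2 ratio on array 3, with a median difference of 0.95, of which 0.46 lay between arrays 1 and 2 and 0.47 between arrays 2 and 3 (medians of member differences). A shift of all genes of an array would move random lists alike, but the median over all tested genes was 0.18 and 95% of 10000 random lists of 48 genes lay between -0.012 and 0.38; none reached 0.95. Differences between the cultures of the 3 arrays, which are independent biological samples, and array effects limited to these genes stay open, and no biological explanation was tested.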
